A study of Mus musculus with 8 samples.

How the data were processed

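The deposited table gives, for each gene and library, a raw count and an FPKM value. Per the file headers, the count values are raw read counts per gene that the authors made before deposit, and the program that counted them is not given in the sources used here. Per the file headers, the FPKM values were deposited by the authors as counts scaled by gene length and library depth. The submitters' notes name FastQC 0.10.1, Bowtie2 2.2.6, HISAT2 2.0.4, SAMtools 1.9, StringTie 1.3.3b and edgeR 3.2.0, without saying which step each served. Per the labels, the libraries were made from total RNA by isolation of mRNA, fragmentation, cDNA synthesis, A-tailing and adapter ligation. The strand, the annotation release and the handling of reads that fit several genes are not given in the sources used here.

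The table lists 34745 genes on GRCm38, with 0 entries lacking a gene and 126 sharing a symbol with another, which were kept apart by Ensembl identifier. Of the identifiers 34267 (98.6%) were found in the reference annotation, 80.8% with an identical span and 98.2% with ends within 10000 bases. Corrected for library depth, the ratio of FPKM to count of a gene was the same in every library to within 0.1% for each of the 9632 genes with at least 100 counts throughout. Depth ran from 11.6 to 24.3 in units of 1e6 counts, and replicate libraries differed from each other by 18.7 to 72.9 times the variance of counting alone, so spread between libraries, not depth, set the precision of abundant genes. Counts were used for every test, and FPKM only to choose which genes to name.

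Genes were kept by filterByExpr with a minimum count of 10 in edgeR 4.0.16 under R 4.3.3, which left 16576. Libraries were scaled by TMM, and the groups were fitted with the quasi-likelihood negative binomial model of edgeR (estimateDisp, glmQLFit with legacy=TRUE and glmQLFTest) with 5 residual degrees of freedom. The 3 comparisons were uIRI against sham, uIRI+MSC against uIRI and uIRI+MSC against sham. P-values were adjusted over all tested genes of a comparison by the method of Benjamini and Hochberg, at 0.05. The SE of a log2 change is its size over the square root of F. DESeq2 1.42.0 and limma-voom (limma 3.58.1) served as other tools. Values in CPM, counts scaled to a library of 1e6, are TMM-scaled, and log2 values of single libraries use a prior count of 2.

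Of 39 gene lists with 695 entries and 667 distinct genes, 693 entries were in the table and 28 genes stood in several lists. Lists with at least 4 tested genes, 38 in all, were tested with camera at a correlation of 0.01, again with an estimated correlation, and with fry. The lists, the comparisons, the threshold, the 14 fixed genes and the rule for naming genes were set before the data were examined. That rule names, per comparison, the 8 largest rises and 8 largest falls past the threshold whose groups do not overlap and whose larger mean FPKM is at least 5, leaving out predicted genes and immunoglobulin and T cell receptor segments. It adds the 14 fixed genes and up to 4 members of each list with the smallest p. Some genes that the rule takes in are not reported here.

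For a gene with 0 counts in 1 group the fold is given as a lower bound with that group set to 3 counts, and with 1 to 3 counts as a ratio with an exact 95% counting interval. Effects of shared libraries were gauged with 20 draws of negative binomial counts, with the fitted dispersions, under no effect or under the injury effect alone. Each gene was drawn independently of the others. The fit was also tested on simulated data in which 200 genes were changed. Alternatives were DESeq2, limma-voom, robust dispersions and legacy=FALSE for the test, median-of-ratios factors or library size alone for the scaling, no filter or at least 50 counts in 2 libraries for the filter, only the 2 groups compared or a replicate block for the design, and leaving out each library in turn. Where that leaves sham with 1 library, the lone sample is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.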

Results

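Gene expression was measured by sequencing of messenger RNA from mouse kidney collected at day 14. The 8 libraries fell into 3 groups, namely sham-operated kidney (n = 2), kidney labelled uIRI (n = 3) and kidney labelled uIRI with transplantation of MSC (n = 3). In the renal literature uIRI stands for unilateral ischaemia-reperfusion injury, in which the blood supply of 1 kidney is clamped and then released, and MSC for mesenchymal stem or stromal cells. The labels spell out neither abbreviation and do not give the source, dose or timing of the cells. In units of 1e6 counts, depth was 24.3, 24.1 and 18.4 for uIRI 1, 2 and 3, 22.7, 13.1 and 11.6 for uIRI+MSC 1, 2 and 3, and 14.6 and 14.2 for sham 1 and 2. Of 34745 genes listed, 11761 had 0 counts in every library and 16576 had enough counts to be tested. Numbers of genes in a gene list are those of the members tested. The labels do not say that the libraries of a group came from separate animals, so every p-value measures only the spread between these samples.

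The libraries separated by group. The first principal component carried 72.8% of the variance and placed sham at 146.9 and 125.2, uIRI+MSC between -29.1 and -19.0, and uIRI between -89.6 and -53.5, with uIRI 1 at the far end. The library uIRI+MSC 3 stood apart on the third component, at -62.3 against -8.3 to 15.1 for all others. Transcripts encoded by mitochondrial DNA made up 14.2% of the counts in both sham libraries, 3.49 to 4.84% in uIRI and 6.07, 6.24 and 11.3% in uIRI+MSC 1, 2 and 3. The 10 most abundant genes took 16.1 and 16.8% of the counts in sham, 4.69 to 6.01% in uIRI and 7.98 to 11.8% in uIRI+MSC.

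**Figure D1:**
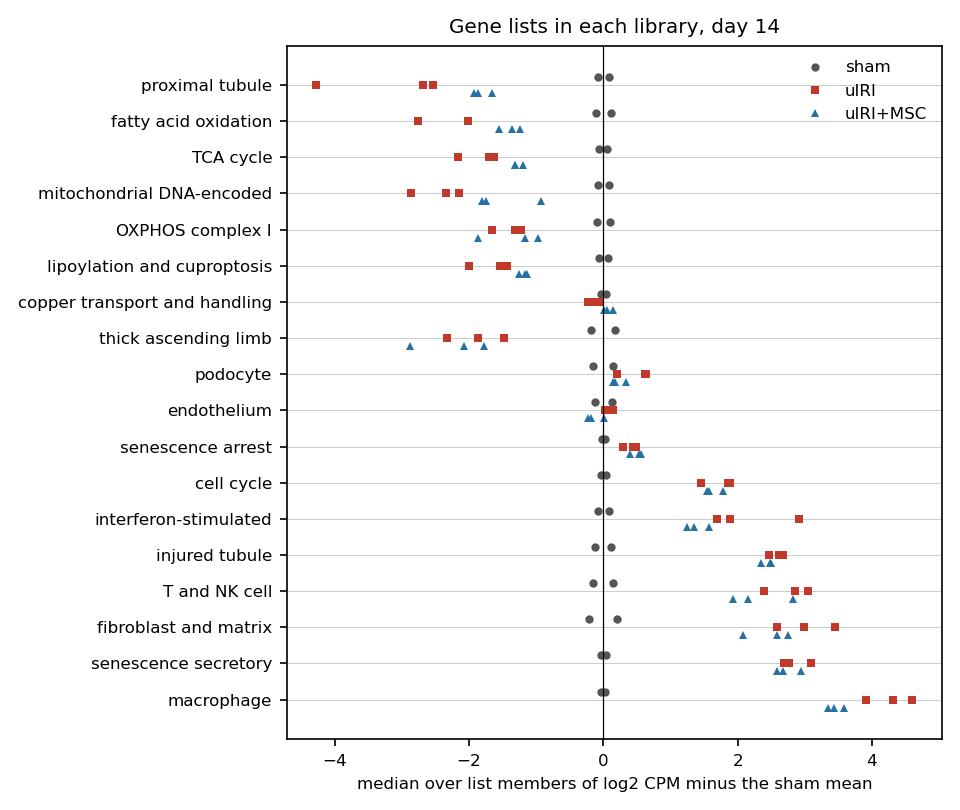
Median over the members of 18 gene lists of log2 CPM (counts scaled to a library of 1e6) minus the sham mean (horizontal axis), with 1 point per library coloured by group. Proximal tubule genes lay between -4.27 and -2.54 in uIRI and between -1.93 and -1.66 in uIRI+MSC, macrophage genes between 3.91 and 4.60 and between 3.35 and 3.58, and the copper list between -0.22 and -0.06 and between 0.01 and 0.14, where its direction depends on the scaling of the libraries.

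The comparison of uIRI with sham asks what the injury had changed in the kidney by day 14. Tubule injury markers were far above sham. Havcr1, which encodes the injury marker KIM-1, reached 311 ± 231 CPM (SD, n = 3) against 3.31 ± 0.126 (n = 2), a log2 fold change of 6.55 ± 0.79 (SE, adjusted p = 0.000231 by edgeR). Without uIRI 2 it was 5.77 ± 0.50. Lcn2, which encodes the iron-carrier-binding protein NGAL, rose by 6.11 ± 0.35 (adjusted p = 2.41e-05), from 3.34 ± 1.01 to 231 ± 34 CPM. Of 28 genes listed for injured tubule, 24 rose, 2 fell and 2 did not pass, with a median log2 change of 2.52, and Cd44 (5.11 ± 0.29) and Vcam1 (4.89 ± 0.31) were among the clearest. The list passed camera at adjusted p = 1.2e-08, with adjusted p = 0.21 with an estimated correlation. On GRCm38, Havcr1 (ENSMUSG00000040405) spans chromosome 11, 46735080 to 46779578, and Lcn2 (ENSMUSG00000026822) chromosome 2, 32384633 to 32388252.

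Across all genes, 9044 of 16576 (54.6%) passed edgeR at an adjusted p of 0.05, of which 4683 were higher and 4361 lower, and 6037 changed at least 2-fold (3511 higher, 2526 lower). At an unadjusted p under 0.05 there were 9987 genes, where 829 would be expected with no difference. The libraries of the 2 groups did not overlap in 12785 genes (77.1%), against 20% by chance for 3 libraries against 2. The split between higher and lower rests on the scaling. With library size alone, and no TMM factors, the median log2 change of all genes was 0.73, -0.16 and 0.55 for uIRI against sham, uIRI+MSC against uIRI and uIRI+MSC against sham, in place of 0.06, -0.01 and 0.03. Under that scaling 11033 genes passed in uIRI against sham, 9044 higher and 1989 lower. All changes given here are relative to the TMM scaling.

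Of the 8 largest rises 7 were in genes with no counts in sham. Retnla, a marker of alternatively activated macrophages, stood at 44.6 ± 19.5 CPM in uIRI, which is at least 301-fold higher when sham is set to a floor of 3 counts over the group. By the same floor the matrix metalloproteinase gene Mmp7 was at least 312-fold higher, a value raised by uIRI 1 (85.0 CPM, against 15.7 and 23.7 in uIRI 2 and 3), the neutrophil chemokine gene Cxcl5 at least 119-fold, Sprr2f at least 81.8-fold, Ms4a4a at least 45.0-fold, the chemokine gene Ccl17 at least 39.8-fold and Il1f6 at least 36.8-fold. Gpnmb had 3 counts in sham and a ratio of 1520 (95% counting interval 521 to 7390). It stood at 379, 38.6 and 217 CPM in uIRI 1, 2 and 3, and its log2 change of 10.48 was 9.74 without uIRI 1. Intervals and floors cover counting error only. Mmp7 and Gpnmb missed the threshold with limma-voom (adjusted p = 0.0581 and 0.0739). Retnla (ENSMUSG00000061100) lies on chromosome 16, 48842552 to 48844461, and Mmp7 (ENSMUSG00000018623) on chromosome 9, 7692090 to 7699585.

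At the other end, Akr1c18, which encodes a hydroxysteroid dehydrogenase, had the largest fall, a change of -9.71 ± 0.55 (adjusted p = 4.73e-05), from 48.2 ± 21.2 to 0.0469 ± 0.0407 CPM. It was followed by Ceacam2 (-9.27), Serpina1d (-8.22), C8a (-7.88), Pvalb (-7.27), Nccrp1 (-7.15), the organic anion transporter gene Slc22a7 (-7.14) and Cyp2a4 (-6.91). Leaving out 1 library took Ceacam2 to -10.59 (uIRI 1), Serpina1d to -9.37 (uIRI 3) or -7.51 (sham 1), and C8a to -8.53 and Slc22a7 to -7.77 (both uIRI 2). It took Pvalb to -6.62 (uIRI 1) or -8.49 (uIRI 3), and Nccrp1 to -7.74 (sham 1) or -6.06 (sham 2). How reads shared by closely related genes were counted is not given in the sources used here, which limits the values of Cyp2a4, Serpina1d, Ceacam2, Sprr2f and the haemoglobin genes. Akr1c18 (ENSMUSG00000021214) lies on chromosome 13, 4132615 to 4150654.

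Genes of the proximal tubule, the segment that reabsorbs most of the filtrate, fell together. All 32 listed genes fell, with a median of -2.97 (camera adjusted p = 7.9e-12, and adjusted p = 0.37 with an estimated correlation). The amino acid transporter gene Slc7a13 (ENSMUSG00000041052, chromosome 4, 19818725 to 19842218) changed by -5.13 ± 0.55 (-5.72 without uIRI 2), Slc22a30 by -4.20 ± 0.48 and Slc17a3 by -3.84 ± 0.44. The list median per library was lowest in uIRI 1, at -4.27, against -2.54 and -2.69 in uIRI 2 and 3. Slc5a2, the glucose transporter gene SGLT2, changed by -1.97 ± 0.45 (adjusted p = 0.00608). In the thick ascending limb 7 of 10 genes fell and 3 did not pass (median -1.86, camera adjusted p = 0.0037, and adjusted p = 0.38 with an estimated correlation), with the growth factor gene Egf at -5.44 ± 0.57 (-6.10 without uIRI 3). Umod, the uromodulin gene, changed by -1.66 ± 0.44 (adjusted p = 0.0117) and lost its call without sham 2 (-1.57, adjusted p = 0.0537) and with library size alone (-1.01, adjusted p = 0.0574).

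Further along the nephron, 7 of 9 distal convoluted tubule genes fell (median -1.42, camera adjusted p = 0.0020, and adjusted p = 0.28 with an estimated correlation), among them the calcium-binding protein gene Calb1 (-4.65 ± 0.61) and the thiazide-sensitive transporter gene Slc12a3 (-2.59 ± 0.28). Of 10 collecting duct principal cell genes 6 fell and St6gal1 rose (1.98 ± 0.19), and the water channel gene Aqp2 changed by -4.32 ± 0.54. The principal cell list (median -0.89) passed camera at adjusted p = 0.036, with adjusted p = 0.43 with an estimated correlation, and lost that call without sham 2 (adjusted p = 0.094). Of 10 intercalated cell genes 5 fell and 1 rose, with a median of -0.65 that became 0.02 with library size alone. This list did not pass (adjusted p = 0.067) but did so without uIRI 3 (0.027), without uIRI+MSC 2 (0.047), without sham 1 (0.031), with library size alone (0.036) and with a replicate block (0.047). Of 10 podocyte genes 4 rose and 6 did not pass (median 0.42, camera adjusted p = 0.060, which became 0.024 without uIRI 2 and 0.019 without sham 2), with Ptpro at 1.23 ± 0.17. Endothelial genes lay at a median of 0.03 with camera leaning down (adjusted p = 0.97). There Eng rose by 0.71 ± 0.14, 11 of 13 did not pass, and Kdr changed by -0.54 ± 0.14, a direction that turned to 0.12 with library size alone and a call that was lost without sham 2 (-0.31, adjusted p = 0.146).

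Transcripts of respiration, which the series names in its title, were followed in lists of its steps, while respiration itself was not measured here. All 29 fatty acid oxidation genes fell, with a median of -2.29 (camera adjusted p = 1e-12, and adjusted p = 0.34 with an estimated correlation), and the medium-chain dehydrogenase gene Acadm (ENSMUSG00000062908, chromosome 3, 153922357 to 153944632) changed by -3.65 ± 0.27, from 1580 ± 393 to 126 ± 34.5 CPM. Of 18 genes of the tricarboxylic acid (TCA) cycle and adjoining steps 17 fell and Pck2 rose (median -1.83, camera adjusted p = 3.7e-08, and adjusted p = 0.35 with an estimated correlation). Of 95 nuclear genes of oxidative phosphorylation (OXPHOS) 75 fell, 20 did not pass and 0 rose, 79 falling when adjusted over the list alone, with a median of -1.29. The medians of complexes I to V were -1.43, -1.54, -1.48, -1.17 and -1.18, and Ndufs1 of complex I changed by -2.15 ± 0.20 and Atp5b of complex V by -1.98 ± 0.25. Each complex passed camera (adjusted p = 7e-09, 0.00044, 0.00071, 7.2e-06 and 0.00013), with adjusted p = 0.37 with an estimated correlation for all but complex II, at 0.28. Of 13 protein genes of mitochondrial DNA 12 fell, and 13 when adjusted over the list alone (median -2.53, camera adjusted p = 2e-05, and adjusted p = 0.36 with an estimated correlation), such as mt-Cytb at -2.54 ± 0.34, beside the fall of the share of all mitochondrial DNA transcripts from 14.2% to 3.49, 4.69 and 4.84% of the counts.

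Of 14 mitochondrial biogenesis genes 7 fell, 6 did not pass and 1 rose (median -0.72, camera adjusted p = 0.0070, and adjusted p = 0.28 with an estimated correlation), with the coactivator gene Ppargc1a at -1.76 ± 0.31 and the deacetylase gene Sirt3 at -2.15 ± 0.30. Of 23 antioxidant genes 19 fell, 20 when adjusted over the list alone, while Slc7a11 and 1 other rose (median -1.50, camera adjusted p = 3.9e-06, and adjusted p = 0.28 with an estimated correlation). Nqo1 changed by -3.18 ± 0.24 and Gclc, an enzyme gene of glutathione synthesis, by -2.62 ± 0.24. Of 18 glycolysis genes 11 fell and 3 rose, the rises being those of the hexokinase genes Hk2 (5.37 ± 0.32, and 6.10 without sham 1) and Hk3 (3.99 ± 0.42) and the lactate transporter gene Slc16a3. Its median was -0.65 (0.00 with library size alone), its mean 0.02, and camera leaned down (adjusted p = 0.055), passing without uIRI 3 (0.047), uIRI+MSC 3 (0.050) or sham 1 (0.035), and with library size alone (0.032). Of 12 heat shock genes 7 fell and 2 rose, among them Hspb1 (2.78 ± 0.43), with a median of -0.87 that did not pass (adjusted p = 0.057) except without uIRI 3 (0.039) or sham 1 (0.032), or with library size alone (0.021).

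Copper genes, a group also named in the title, went both ways. Slc31a1 (ENSMUSG00000066150, chromosome 4, 62360727 to 62391769), the plasma membrane copper importer CTR1, changed by -1.54 ± 0.17 (adjusted p = 0.000145), from 293 ± 34.6 to 101 ± 17.9 CPM. The copper-exporting ATPase gene Atp7b (ENSMUSG00000006567, chromosome 8, 21992785 to 22060305) changed by -2.23 ± 0.36 (adjusted p = 0.000992), while Atp7a did not pass (0.27 ± 0.21, adjusted p = 0.302, and 0.92 at adjusted p = 0.00574 with library size alone). The metallothionein genes Mt2 (ENSMUSG00000031762, chromosome 8, 94172618 to 94173567) and Mt1 rose by 2.58 ± 0.26 (adjusted p = 0.000112) and 0.91 ± 0.22 (adjusted p = 0.00695), the latter without a call when sham 2 was left out (0.80, adjusted p = 0.0566). Of the 35 genes tested among 38 listed, 13 rose, 14 fell (15 when adjusted over the list alone) and 8 did not pass. The rises included Cp, which encodes ceruloplasmin (3.59 ± 0.18), and the copper-dependent lysyl oxidase genes Loxl3 (3.70 ± 0.27) and Loxl1 (3.13 ± 0.23). The list did not pass camera (adjusted p = 0.97), with a median of -0.16 (0.51 with library size alone), a mean of 0.45, camera leaning down and fry up (adjusted p = 0.013). Genes of lipoylation, the step at which copper toxicity acts in cuproptosis, fell in 12 of 15 cases (median -1.63, camera adjusted p = 5e-07, and adjusted p = 0.33 with an estimated correlation), such as Gcsh at -2.07 ± 0.13 and Dlat at -1.81 ± 0.14. Fdx1 (ENSMUSG00000032051, chromosome 9, 51943307 to 51963533), the ferredoxin of that step, changed by -2.03 ± 0.29 (adjusted p = 0.000521).

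For senescence, the remaining subject of the title, arrest and secretory genes were listed apart. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090979 to 29100722), which encodes the cell cycle inhibitor p21, rose by 2.19 ± 0.21 (adjusted p = 7.95e-05), from 14.1 ± 3.54 to 64.1 ± 10.1 CPM. Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), the gene of p16 and p19, had 1 count in sham and 1.86 ± 0.91 CPM in uIRI, a ratio of 40.6 (95% counting interval 7.17 to 1610, adjusted p = 0.00143). Its log2 change of 5.12 was 4.27 without sham 1. Without sham 2 the remaining sham library had 0 counts, so the fitted value of 8.20 is not an exact change. Of 17 senescence arrest genes 8 rose, 3 fell and 6 did not pass (median 0.39, camera adjusted p = 0.18). Fry passed this list as higher (adjusted p = 0.00067), but it passed 33 of the 38 lists. The 3 that fell were Glb1 (-1.59 ± 0.20), the gene of the beta-galactosidase used as a senescence stain, Ccng1 and Sesn2. Lmnb1, whose loss is used as a sign of senescence, rose by 1.70 ± 0.20. Of 41 senescence secretory genes 33 rose, 34 when adjusted over the list alone, and 4 fell, among them Igfbp3, Igfbp5 and Vegfa (median 3.27, camera adjusted p = 3.7e-08, and adjusted p = 0.21 with an estimated correlation). The median was 2.81 with the 7 genes that had no counts in 1 group set at their bound. Among the clearest were the metalloproteinase gene Mmp14 (4.20 ± 0.32), the cytokine gene Lif (4.63 ± 0.34) and the chemokine gene Cxcl16 (2.32 ± 0.17).

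Immune and matrix genes were higher as groups. All 21 macrophage genes rose (median 4.33, camera adjusted p = 7.8e-13, and adjusted p = 0.21 with an estimated correlation). The fractalkine receptor gene Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120068283) went from 8.55 ± 0.277 to 137 ± 7.81 CPM, a 16.0-fold rise with an adjusted p of 1.79e-05. All 29 fibroblast and matrix genes rose (median 3.07, camera adjusted p = 3.2e-11, and adjusted p = 0.35 with an estimated correlation), with Fn1 at 4.88 ± 0.45 and Tgfb1 at 2.61 ± 0.19, and the collagen gene Col1a1 at 4.51 ± 0.52 (adjusted p = 0.00019). Of 17 complement genes 14 rose and 1 fell (median 3.47, camera adjusted p = 3.6e-06, and adjusted p = 0.21 with an estimated correlation), and C1qa changed by 4.37 ± 0.27. Of 22 T and NK cell genes 19 rose, 21 when adjusted over the list alone (median 2.84, camera adjusted p = 1.3e-07, and adjusted p = 0.33 with an estimated correlation), with Cd3e at 3.40 ± 0.33 (4.04 without sham 2). All 6 neutrophil genes tested of 13 listed rose (median 3.50, 4.67 without sham 2, camera adjusted p = 0.0037, and adjusted p = 0.28 with an estimated correlation). Of 15 B and plasma cell genes 7 rose and 1 fell (median 1.61, camera adjusted p = 0.020, and adjusted p = 0.38 with an estimated correlation), a call lost without sham 1 (median 0.93, adjusted p = 0.12) and with library size alone (0.19).

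Other responses were also higher. Of 24 interferon-stimulated genes 22 rose (median 2.28, camera adjusted p = 1.8e-06, and adjusted p = 0.38 with an estimated correlation), with Mx1 at 3.55 ± 0.47. Of 25 cell cycle genes 23 rose (median 1.92, camera adjusted p = 1.1e-07, and adjusted p = 0.21 with an estimated correlation), with the topoisomerase gene Top2a at 2.31 ± 0.19 and the replication helicase gene Mcm3 at 2.44 ± 0.16. Of 17 immediate early genes 14 rose (median 1.68, camera adjusted p = 0.00018, and adjusted p = 0.35 with an estimated correlation), with Atf3 at 4.88 ± 0.40 (5.51 without sham 2).

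Lists for tissues that could be carried along in dissection were small. Of 7 liver genes 4 fell, namely Alb (-4.10 ± 0.61, and -4.76 without uIRI 2), Ttr (-3.47, and -2.81 without sham 1), Apoa2 and Serpina1a (median -2.11, camera adjusted p = 0.044, and adjusted p = 0.40 with an estimated correlation), a call lost without uIRI 1 (adjusted p = 0.12). Serpina1a itself (-2.11 ± 0.64) lost its call without uIRI 1 (adjusted p = 0.0573), without sham 1 (0.124) and with library size alone (0.0624). Of 7 erythrocyte genes 0 passed edgeR (median -1.75, camera adjusted p = 0.18), 0 when adjusted over the list alone. The median was -2.48 without sham 1 (adjusted p = 0.013) and -0.10 without sham 2 (adjusted p = 0.68). The 4 adipocyte genes had a median of -0.18 (0.48 with library size alone, 0.47 without sham 1 and 0.45 without sham 2) and adjusted p = 0.42, the 4 skeletal muscle genes a median of 1.32 (2.91 without sham 2), a mean of -0.43 and adjusted p = 0.92, and the 2 adrenal genes, Cyp21a1 and Star, did not pass, though Cyp21a1 (adjusted p = 0.0540) did so without uIRI+MSC 3 (0.0337) and with DESeq2 (0.0303) and limma-voom (0.0323). The 4 Y-linked genes had detectable counts and a median of -0.33 (0.34 with library size alone, camera adjusted p = 0.42). Among them Eif2s3y (-0.52 ± 0.19) and Uty (-0.48 ± 0.16) passed, and turned to 0.15 and 0.19 with library size alone. Eif2s3y lost its call without any 1 of uIRI 1, uIRI 2, uIRI 3, uIRI+MSC 2, sham 1 or sham 2 (adjusted p = 0.0661 to 0.294), and Uty without any 1 of the uIRI or sham libraries (adjusted p = 0.0538 to 0.158).

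In all, camera called 27 of 38 lists in uIRI against sham, 11 higher and 16 lower, at its preset correlation of 0.01. With an estimated correlation 0 lists passed in any of the 3 comparisons, the smallest adjusted p being 0.21, 0.43 and 0.14. The test fry, which asks whether a list's genes move on balance in 1 direction and does not set them against other genes, passed 33 lists here, and its mixed form, for change in either direction, 36. Members named because they moved against the rest of their list or fell short of the main threshold, and that are not in the set of genes fixed by rule, were chosen after their values were seen.

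The comparison of uIRI+MSC with uIRI asks what the transplanted cells added to the injury. Kidneys that received MSC held fewer macrophage transcripts and more transcripts of the proximal tubule and of fatty acid oxidation, as groups by camera at its preset correlation, while 0 genes passed edgeR individually. All 3 of these camera calls were lost with an estimated correlation, at adjusted p = 0.43, 0.52 and 0.52. The test fry passed the macrophage list (adjusted p = 0.036) but not the proximal tubule (0.13) or fatty acid oxidation list (0.083). The smallest adjusted p was 0.111, so for each gene named here the difference is given with its error and was not called. Cx3cr1 was at 82.7 ± 4.91 CPM (SD, n = 3) against 137 ± 7.81 in uIRI (n = 3), a log2 difference of -0.73 ± 0.11 (SE). Cyp2e1, a proximal tubule cytochrome gene, was at 743 ± 127 against 179 ± 108 CPM (2.05 ± 0.46), and the mitochondrial carnitine transferase gene Cpt2 at 76.0 ± 7.98 against 34.9 ± 9.51 CPM (1.12 ± 0.21). In each of these 3 genes the difference had the same sign for all 3 libraries of a group against all 3 of the other.

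At an unadjusted p under 0.05 there were 3418 genes, 1869 higher and 1549 lower, where 829 would be expected with no difference. Mixed groupings of the uIRI and uIRI+MSC libraries, chosen after the result was seen, gave 185 to 1574 such genes with edgeR. Of these, 994 (uIRI+MSC 3 with uIRI 1 and 2) and 1574 (uIRI+MSC 3 with uIRI 1 and 3) lay above 829, and the others were 663 or fewer. A mixed grouping keeps part of any real difference between the groups. These counts thus cannot show how many genes would pass with no effect. Limma-voom called 0 genes and DESeq2 1341, 781 higher and 560 lower. The libraries of the 2 groups did not overlap in 4451 genes (26.9%), against 10% by chance. In edgeR the count went from 0 to 8 without uIRI 1, to 3 without uIRI 3, to 2 without uIRI+MSC 1 and to 2 without uIRI+MSC 3. The 8 were Phc3, Sirpa, Cyp4a31, Dpys, Cyp2a5, F13b, Pck1 and Cyp2d12, the 3 included Zfp422 and Sepsecs, and the pairs were Rab22a with Tmem168 and Pdk4 with Angptl4. All but Pck1 were named after their values were seen. Pck1, the gene of the gluconeogenic enzyme PEPCK, was at 640 ± 103 against 127 ± 83.3 CPM (2.33 ± 0.53), and at 1.87 ± 0.21 with adjusted p = 0.0396 without uIRI 1.

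Proximal tubule genes lay above uIRI in 32 of 32 cases (median 1.21), 27 of them past the threshold when adjusted over the list alone. Camera called the list at adjusted p = 9.1e-17, with adjusted p = 0.52 with an estimated correlation. The organic anion transporter gene Slc22a6 differed by 2.05 ± 0.50 and Slc17a3 by 1.79 ± 0.39. All 29 fatty acid oxidation genes lay above uIRI (median 0.79), 24 past the threshold when adjusted over the list alone (camera adjusted p = 9.1e-17, and adjusted p = 0.52 with an estimated correlation), such as Acad11 at 0.95 ± 0.20 and Decr1 at 0.72 ± 0.16. All 18 TCA cycle genes lay above uIRI (median 0.51), 15 past the threshold when adjusted over the list alone (camera adjusted p = 1.5e-09, and adjusted p = 0.52 with an estimated correlation), with Suclg2 at 1.23 ± 0.27. Lists of lipoylation (median 0.45, 7 of 15 adjusted over the list alone, camera adjusted p = 5.7e-06) and antioxidant genes (median 0.49, 13 of 23 adjusted over the list alone, camera adjusted p = 8.4e-06) were also called higher, with adjusted p = 0.52 with an estimated correlation for both. Gclc differed by 1.21 ± 0.21, Nqo1 by 1.06 ± 0.22 and Pdha1, a pyruvate dehydrogenase subunit gene, by 0.61 ± 0.14. The library uIRI 1, lowest in proximal tubule, fatty acid oxidation and TCA cycle genes (medians of -4.27, -2.76 and -2.17 against sham), moves with these differences.

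The 13 mitochondrial DNA genes had a median of 1.00, 9 of them past the threshold when adjusted over the list alone (camera adjusted p = 0.00012, and adjusted p = 0.57 with an estimated correlation), with mt-Nd5 at 1.41 ± 0.39 (0.86 without uIRI+MSC 3). The share of mitochondrial DNA transcripts was highest in uIRI+MSC 3, at 11.3%, and without that library the median was 0.65 (camera adjusted p = 0.0039). The 95 nuclear OXPHOS genes had a median of 0.13, and 0 passed the threshold when adjusted over these genes alone. Complex II was called (median 0.31, adjusted p = 0.034, and adjusted p = 0.57 with an estimated correlation), and not so without uIRI 1 (adjusted p = 0.077), uIRI+MSC 1 (0.15) or uIRI+MSC 2 (0.093), or with a replicate block (0.052). Complexes I, III, IV and V were not called, with medians of 0.07, 0.07, 0.09 and 0.13 that turned to -0.07, -0.07, -0.05 and -0.02 with library size alone. Those of complexes I, III and IV also turned to -0.08, -0.02 and -0.03 without uIRI 1, and to -0.13, -0.21 and -0.13 without uIRI+MSC 1. Without uIRI+MSC 3 these 4 complexes were called, at medians of 0.30, 0.39, 0.28 and 0.28 (adjusted p = 1.1e-05, 0.010, 0.0013 and 0.0064). Uqcrc2 of complex III (0.60 ± 0.16) passed when adjusted over the list alone. Mitochondrial biogenesis genes were called higher (median 0.34, adjusted p = 0.0011, and adjusted p = 0.43 with an estimated correlation), 4 of 14 when adjusted over the list alone, namely Ppargc1b (0.73 ± 0.18), Pprc1 (0.69 ± 0.18), Polrmt (0.47 ± 0.13) and Tfb2m (0.54 ± 0.17), while Ppargc1a differed by 0.75 ± 0.28 (adjusted p = 0.189, and 0.47 without uIRI+MSC 3).

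Macrophage genes lay below uIRI in 21 of 21 cases (median -0.89), 17 of them past the threshold when adjusted over the list alone (camera adjusted p = 9.8e-13, and adjusted p = 0.43 with an estimated correlation). C1qa differed by -1.04 ± 0.19, from 432 ± 109 to 211 ± 20.2 CPM, and Ms4a7 by -0.96 ± 0.20. Of 17 complement genes, 9 lay lower and 3 higher when adjusted over the list alone (median -0.57, camera adjusted p = 0.0047, and adjusted p = 0.43 with an estimated correlation). The lower genes included the receptor gene C3ar1 (-1.06 ± 0.21), and the higher ones were C3 (1.28), Cfb (1.12) and Cfi (1.22). Interferon-stimulated genes had a median of -0.87, 10 of 24 lower when adjusted over the list alone (camera adjusted p = 2.5e-06, and adjusted p = 0.58 with an estimated correlation), with Oas1a at -1.50 ± 0.32 and Isg15 at -1.70 ± 0.43. The library uIRI 3 stood apart in this list (median 2.91 against sham, with 1.89 and 1.69 in uIRI 1 and 2). Without it the list median was -0.26 (camera adjusted p = 0.0023) and Isg15 differed by -1.07 ± 0.31. The fibroblast and matrix list had 0 of 29 genes above uIRI (median -0.63, camera adjusted p = 1.3e-07, and adjusted p = 0.58 with an estimated correlation), with 0 past the threshold when adjusted over the list alone and a median of -0.38 without uIRI 1. Col6a1 differed by -0.91 ± 0.27, Ctgf by -0.90 ± 0.26 and Col1a1 by -0.95 ± 0.38 (adjusted p = 0.209, and -0.49 without uIRI 1).

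T and NK cell genes were called lower (median -0.41, adjusted p = 0.0031, and adjusted p = 0.58 with an estimated correlation), a call lost without uIRI 1 and uIRI+MSC 3 together (adjusted p = 0.17). Its median was -0.70 without uIRI+MSC 2. Neutrophil genes were called lower (median -0.73, adjusted p = 0.022, and adjusted p = 0.52 with an estimated correlation), with only Ltf (-1.65 ± 0.38) passing when adjusted over the list alone, a list call lost without uIRI+MSC 2 (adjusted p = 0.15) and with library size alone (0.068). Podocyte genes (median -0.27, adjusted p = 0.034) and endothelial genes (median -0.20, adjusted p = 0.034) were called lower, with adjusted p = 0.58 with an estimated correlation for both. The podocyte call was lost without uIRI 1 (0.054), uIRI 3 (0.091), uIRI+MSC 1 (0.097) or uIRI+MSC 3 (0.050), and the endothelial call without uIRI 3 (0.091) or uIRI+MSC 2 (median -0.12, adjusted p = 0.23). Thick ascending limb genes were called lower (median -0.67, adjusted p = 0.042, and adjusted p = 0.72 with an estimated correlation), with the claudin gene Cldn16 at -1.01 ± 0.28. That call was lost without uIRI 2 (0.082), uIRI 3 (median -0.44, adjusted p = 0.23), uIRI+MSC 1 (0.083), uIRI+MSC 2 (median -0.33, adjusted p = 0.24), sham 1 (0.056) or sham 2 (0.055), and with library size alone (0.097). The median was -1.01 without uIRI+MSC 3. Liver-listed genes were called higher (median 1.13, 0.68 without uIRI 1 and 1.80 without uIRI 2, adjusted p = 0.0042, and adjusted p = 0.56 with an estimated correlation), where the 3 genes past the threshold adjusted over the list alone were the fibrinogen chains Fga (2.22 ± 0.67), Fgb (2.23 ± 0.60) and Fgg (2.49 ± 0.78). Without uIRI 2 these 3 differed by 3.33 ± 0.56, 3.17 ± 0.53 and 3.73 ± 0.71.

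Of the 3 subjects in the title, the senescence arrest list was not called (median 0.03, -0.14 with library size alone, mean -0.16, camera adjusted p = 0.57, fry adjusted p = 0.29, and 0.023 in the mixed form of fry). Within it Cdkn1a (40.0 ± 2.02 against 64.1 ± 10.1 CPM, -0.68 ± 0.17), Cdkn2a (0.506 ± 0.0787 against 1.86 ± 0.91 CPM, -1.85 ± 0.48), Cdkn2b (-1.23 ± 0.30) and Btg2 (-0.60 ± 0.16) lay lower and Glb1 (0.60) higher when adjusted over the list alone. Over all genes the adjusted p was 0.112 for Cdkn1a and 0.120 for Cdkn2a by edgeR, and 0.00861 and 0.0313 by DESeq2. The secretory list had a median of -0.08 (adjusted p = 0.36), with 0 of 41 genes past the threshold when adjusted over the list alone. Copper genes had a median of 0.09 (-0.06 with library size alone, adjusted p = 0.55), also with 0 of 35. Slc31a1 was at 148 ± 1.71 against 101 ± 17.9 CPM (0.56 ± 0.15, adjusted p = 0.123 by edgeR and 0.0281 by DESeq2). Atp7b differed by 1.01 ± 0.33 (adjusted p = 0.156), Atp7a by 0.07 ± 0.18, Mt1 by -0.53 ± 0.19, Mt2 by -0.56 ± 0.21 and Fdx1 by 0.45 ± 0.26. Injured tubule genes had a median of 0.08 (-0.07 with library size alone, adjusted p = 0.36). In that list Havcr1 was at 885 ± 372 against 311 ± 231 CPM (1.51 ± 0.50, adjusted p = 0.158 by edgeR and 0.0259 by DESeq2, with 2.29 ± 0.39 without uIRI 2). Havcr1 stood at 572 CPM in uIRI 2 against 135 and 227 in uIRI 1 and 3. Lcn2 was at 156 ± 42.8 against 231 ± 34 CPM (-0.56 ± 0.22). Umod differed by -0.49 ± 0.40 (-0.14 without uIRI+MSC 2 and -0.89 without uIRI+MSC 3) and Slc5a2 by 0.51 ± 0.41 (0.13 without uIRI 1 and 0.84 without uIRI 2).

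**Figure D2:**
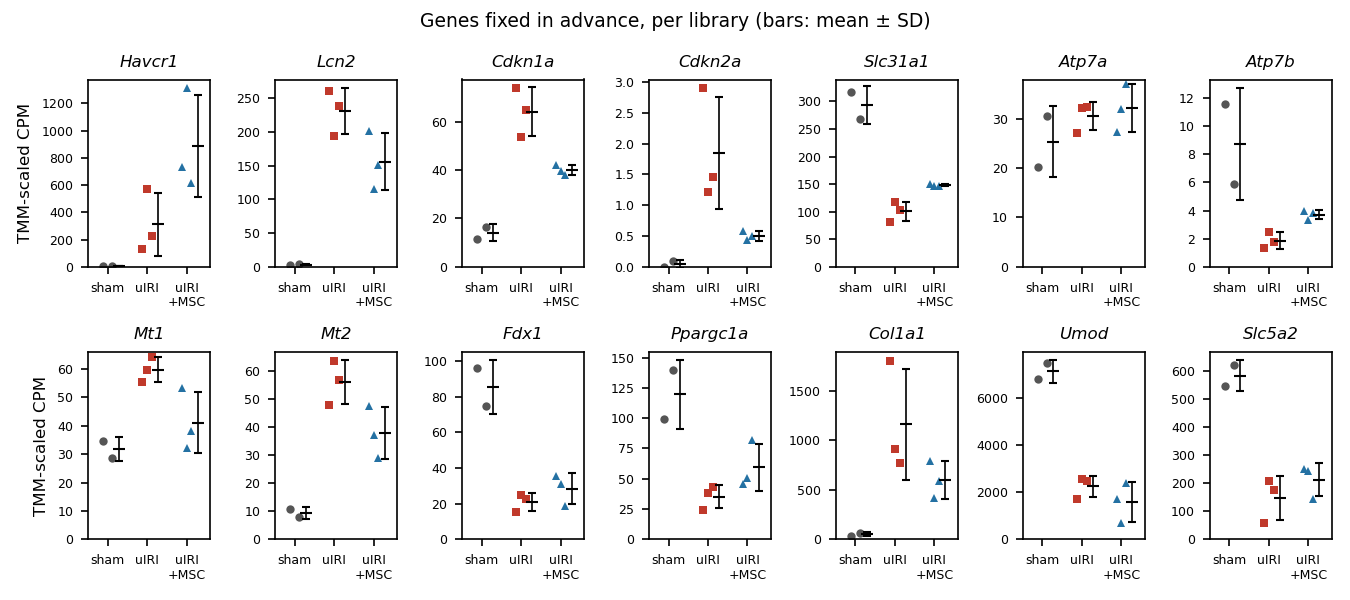
TMM-scaled CPM (vertical axis, from 0) of 14 genes fixed in advance, with 1 point per library for sham, uIRI and uIRI+MSC, and bars for the mean ± SD. Slc31a1 lay at 293 ± 34.6 in sham, 101 ± 17.9 in uIRI and 148 ± 1.71 in uIRI+MSC, and Havcr1 at 3.31 ± 0.126, 311 ± 231 and 885 ± 372.

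The lists not called otherwise had medians of -0.03 (glycolysis, with Hk2 at -1.10 ± 0.20 and Hk3 at -1.19 ± 0.29 lower when adjusted over the list alone), -0.09 (cell cycle), 0.26 (distal convoluted tubule), -0.11 (intercalated cells, where camera also leaned down and the mean was 0.00), -0.42 (B and plasma cells), 0.41 (erythrocytes, with -0.35 without uIRI+MSC 2 and 0.23 to 0.75 without any 1 of uIRI 1, uIRI 3, uIRI+MSC 1 or uIRI+MSC 3), 0.75 (adipocytes, of which only Pck1 passed when adjusted over the list alone), -0.34 (skeletal muscle, with -0.10 without uIRI 2 and -0.90 without uIRI+MSC 2) and 0.18 (Y-linked). Immediate early genes (median -0.20, adjusted p = 0.17, with Egr3 and Ier2 lower when adjusted over the list alone) were called without uIRI+MSC 3 (-0.32, adjusted p = 0.0068). Without uIRI+MSC 1 their median turned to 0.03 (adjusted p = 0.8). Principal cell genes (median 0.35, adjusted p = 0.17) and heat shock genes (median 0.15, adjusted p = 0.11) were called without uIRI 3 (adjusted p = 0.020 and 0.036). The principal cell median was 0.61 there, but 0.12 without uIRI 1 (adjusted p = 0.36) and 0.1 without uIRI+MSC 2 (0.3). The adrenal genes Cyp21a1 and Star did not pass. In all camera called 18 of 38 lists, 9 higher and 9 lower, and fry called 3, the macrophage, complement and mitochondrial biogenesis lists (adjusted p = 0.036 for each), with 14 in its mixed form.

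Whether expression after MSC lay nearer to sham was asked across genes. Of the 9044 genes called in uIRI against sham, 87.0% differed in the opposite direction between uIRI+MSC and uIRI. Both changes use the same uIRI libraries. Simulated data with the injury effect but no effect of MSC gave 55.39% (54.63 to 56.24% in 20 draws). Part of the excess over an even split thus comes from the shared libraries. Genes were drawn independently there, so this range leaves out shifts that many genes share. The covariance of the log2 changes over the 16576 genes was -0.63, against -0.06 in data simulated with no effect, a difference of -0.57. Pearson's r across genes was -0.61, where genes are not independent replicates. Leaving out 1 library at a time gave 82.8 to 89.4%. With 1 uIRI library set against sham and the other 2 set against uIRI+MSC, so that no uIRI library was shared, 84.3, 87.7 and 90.2% of the called genes ran opposite.

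**Figure D3:**
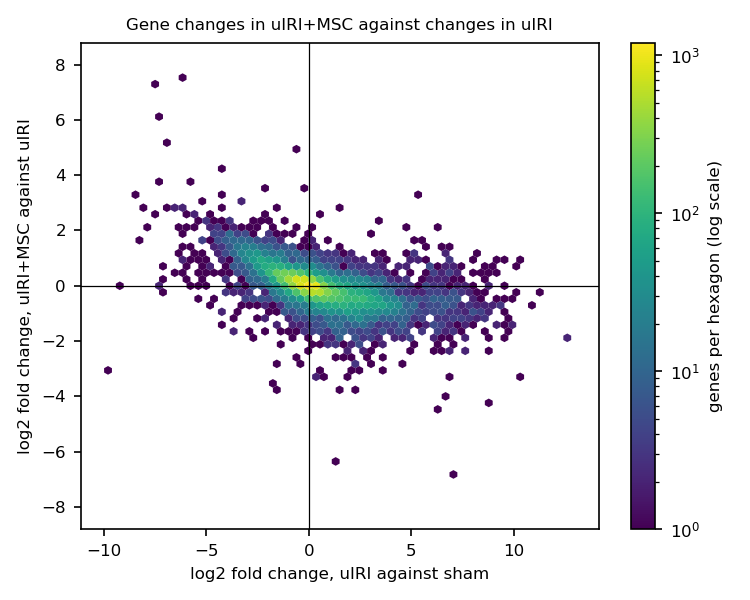
Log2 fold change of uIRI+MSC against uIRI (vertical axis) over that of uIRI against sham (horizontal axis) for 16576 genes, binned in hexagons coloured by the number of genes on a log scale. The cloud slopes downward, with 87.0% of the 9044 genes called in uIRI against sham on the opposite side of 0 on the vertical axis.

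The comparison of uIRI+MSC with sham asks what difference from uninjured kidney was left after treatment. Injury markers and immune transcripts were still high. Havcr1 was at 885 ± 372 CPM (SD, n = 3) against 3.31 ± 0.126 in sham (n = 2), a rise of 8.06 ± 0.84 (SE, adjusted p = 0.000242 by edgeR), and Lcn2 rose by 5.54 ± 0.34. Macrophage genes rose in 21 of 21 cases (median 3.40, camera adjusted p = 2.8e-14, and adjusted p = 0.14 with an estimated correlation), with Cx3cr1 at 3.27 ± 0.14. Proximal tubule genes fell in 28 of 32 cases (median -1.78, camera adjusted p = 9.5e-09, and adjusted p = 0.38 with an estimated correlation), with Slc7a13 at -3.43 ± 0.52, and fatty acid oxidation genes in 27 of 29 (median -1.39, camera adjusted p = 1.5e-10, and adjusted p = 0.30 with an estimated correlation), with Acadm at -2.71 ± 0.26.

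Over all genes 7029 of 16576 (42.4%) passed edgeR, 3671 higher and 3358 lower, and 4476 changed at least 2-fold (2738 higher, 1738 lower). At an unadjusted p under 0.05 there were 8477. The count fell to 3938 without sham 1. With library size alone 8752 genes passed, 7400 higher and 1352 lower. The libraries did not overlap in 64.2% of genes, against 20% by chance. Of these genes 3492 were higher and 3182 lower in both injured groups against sham, where independent lists of these sizes would share 1037 and 883, and 0 genes had calls in opposite directions. Both comparisons use the same sham libraries. Data simulated with the injury effect and none of MSC gave 3882.3 and 3277.3 shared genes, and data with no effect gave 0 and 0. The covariance of the changes was 2.65 against 0.12 with no effect, and the correlation across genes 0.955 against 0.66. With the injury effect and none of MSC they were higher than observed, at 3.02 (2.98 to 3.06) and 0.98. Genes were drawn independently in all these simulations.

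Of the 8 largest rises 7 were also among the 8 in uIRI, and 7 of the 8 largest falls. By the floor of 3 counts over the sham group, Cxcl5 was at least 96.9-fold higher, Retnla at least 74.4-fold, Mmp7 at least 72.0-fold, Il1f6 at least 65.3-fold, Sprr2f at least 55.8-fold, Ms4a4a at least 34.0-fold and Ccl17 at least 22.8-fold. Mmp7 lost its call without sham 1 (adjusted p = 0.0803) or sham 2 (0.0713), as did Ccl17 (0.0772 and 0.0683), and limma-voom called neither (0.149 and 0.0768). At the lower end Akr1c18 had 0 counts in uIRI+MSC and was at least 793-fold lower, and Ceacam2 had a ratio of 714 of sham over uIRI+MSC (243 to 3470). Nccrp1 (-7.40), Slc22a7 (-7.04), Pvalb (-6.65), Serpina1d (-6.53), Mettl7a2 (-6.15) and C8a (-5.89) followed. Leaving out 1 library took Nccrp1 to -6.32 (sham 2), Pvalb to -6.01 (uIRI+MSC 1) or -8.80 (uIRI+MSC 2), Serpina1d to -7.63 (uIRI+MSC 3) or -5.81 (sham 1), and Mettl7a2 to -6.78 (uIRI+MSC 3) or -5.56 (sham 1).

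Of the inflammatory and repair lists, 24 of 29 fibroblast and matrix genes rose (median 2.53, camera adjusted p = 4.8e-11, and adjusted p = 0.30 with an estimated correlation), with Col1a1 at 3.56 ± 0.50. Of 28 injured tubule genes 23 rose and 5 did not pass (median 2.21, camera adjusted p = 1.6e-11, and adjusted p = 0.14 with an estimated correlation), with Vcam1 at 5.74 ± 0.32. Of 41 secretory genes 32 rose, and 4 fell, among them Igfbp5 (median 3.42, or 2.49 with 7 genes at their bound, camera adjusted p = 6.8e-10, and adjusted p = 0.14 with an estimated correlation), with Lif at 4.86 ± 0.35. Of 24 interferon-stimulated genes 14 rose (median 1.27, camera adjusted p = 8.3e-05, and adjusted p = 0.44 with an estimated correlation), with Cxcl10 at 3.95 ± 0.45. Of 25 cell cycle genes 23 rose (median 1.69, camera adjusted p = 6.6e-09, and adjusted p = 0.15 with an estimated correlation), with Top2a at 2.30 ± 0.19. Of 17 complement genes 14 rose and 1 fell (median 2.83, camera adjusted p = 1.3e-07, and adjusted p = 0.14 with an estimated correlation). T and NK cell genes (19 of 22, median 2.47, camera adjusted p = 4.5e-08), neutrophil genes (5 of 6, median 2.78, adjusted p = 0.0072) and immediate early genes (11 of 17, median 1.23, adjusted p = 7.8e-05) rose, each with adjusted p = 0.30 with an estimated correlation. The neutrophil call was lost with library size alone (0.053), and its median was 3.98 without sham 2. B and plasma cell genes rose in 5 of 15 cases (median 0.85, adjusted p = 0.030, and adjusted p = 0.41 with an estimated correlation), a call lost without sham 1 (median 0.42, adjusted p = 0.23) and with library size alone (0.25). Its median was 2.05 without sham 2.

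Of 18 TCA cycle genes 17 fell and Pck2 rose (median -1.25, camera adjusted p = 2.2e-07, and adjusted p = 0.30 with an estimated correlation). Of 95 nuclear OXPHOS genes 75 fell, 80 when adjusted over these genes alone (median -1.23), with Ndufs1 at -1.51 ± 0.20, and complexes I to V were each called (adjusted p = 4.8e-11, 0.00025, 0.00013, 1.1e-06 and 2e-05, and adjusted p = 0.30 with an estimated correlation for each). Of 13 mitochondrial DNA genes 12 fell (median -1.49, camera adjusted p = 0.00019, and adjusted p = 0.33 with an estimated correlation), where the share of their transcripts was 6.07 to 11.3% against 14.2%. Lipoylation genes fell in 12 of 15 cases (median -1.19, camera adjusted p = 7.1e-07), antioxidant genes in 14 of 23 with 1 rising (median -1.13, adjusted p = 7.8e-05) and glycolysis genes in 12 of 18 with Hk2, Hk3 and Slc16a3 rising (median -0.72, adjusted p = 0.015), each with adjusted p = 0.30 with an estimated correlation. Mitochondrial biogenesis genes had 7 falls and the rise of Pprc1 (median -0.33, 0.18 with library size alone) and did not pass (adjusted p = 0.052), but did so without uIRI 3 (0.049), uIRI+MSC 2 (0.047) or sham 2 (0.034), and with a replicate block (0.041). Ppargc1a changed by -1.01 ± 0.31 (adjusted p = 0.0278) and lost its call without uIRI+MSC 1 (0.0800), uIRI+MSC 2 (0.0781), sham 1 (0.0563) or sham 2 (0.199), and with library size alone (0.175). Heat shock genes had 5 falls and the rise of Hspb1 (median -0.59, adjusted p = 0.073, 0.049 without sham 1, and 0.029 with library size alone).

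Along the rest of the nephron, 9 of 10 thick ascending limb genes fell (median -2.04, camera adjusted p = 2.1e-05, and adjusted p = 0.30 with an estimated correlation), with Egf at -5.48 ± 0.57, Ptger3 at -2.85 ± 0.33 and Umod at -2.16 ± 0.44 (adjusted p = 0.0051). Distal convoluted tubule genes fell in 7 of 9 cases, with 1 rising (median -1.24, adjusted p = 0.0013, and adjusted p = 0.30 with an estimated correlation). Intercalated cell genes fell in 5 of 10 cases (median -0.73, adjusted p = 0.037, and adjusted p = 0.44 with an estimated correlation), a call lost without uIRI+MSC 1 (0.064) or sham 2 (0.089). Principal cell genes had 4 falls and the rise of St6gal1 (median -0.75) and did not pass (adjusted p = 0.074), but did so without uIRI 1 (0.039), uIRI 3 (0.050), uIRI+MSC 2 (0.049) or sham 1 (0.024), with library size alone (0.011) and with a replicate block (0.017). Podocyte genes (median 0.18, 3 rises, among them Ptpro) and endothelial genes (median -0.17, 0.35 with library size alone) were not called (adjusted p = 0.24 and 0.31). Slc5a2 changed by -1.46 ± 0.45 (adjusted p = 0.0301) and lost its call without uIRI+MSC 1 (0.0531), uIRI+MSC 2 (0.0537), uIRI+MSC 3 (0.0916), sham 1 (0.0994) or sham 2 (with a change of -1.32 ± 0.58), with library size alone (0.0981) and with a replicate block (0.0581).

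In the senescence arrest list 6 genes rose, 8 when adjusted over the list alone, and 3 fell (median 0.47, camera adjusted p = 0.11). Fry passed this list as higher (adjusted p = 0.0022), but it passed 30 of the 38 lists. Cdkn1a rose by 1.50 ± 0.20 (adjusted p = 0.000709). Cdkn2a had a ratio of 11.0 over 1 count in sham (95% counting interval 1.82 to 453, adjusted p = 0.0312), a call lost without uIRI+MSC 1 (0.0690), uIRI+MSC 3 (0.0509) or sham 1 (0.157), and with DESeq2 (0.0695), limma-voom (0.0618) or edgeR with legacy=FALSE (0.0705). Its log2 change of 3.27 was 2.43 without sham 1. Without sham 2 the remaining sham library had 0 counts, so the fitted value of 6.37 is not an exact change. Of 35 copper genes 9 rose, 10 when adjusted over the list alone, and 11 fell (median 0.04, camera adjusted p = 0.81). Slc31a1 changed by -0.98 ± 0.17 (adjusted p = 0.00216), Fdx1 by -1.58 ± 0.29 and Mt2 by 2.02 ± 0.26. The genes Mt1 (0.38 ± 0.21, adjusted p = 0.185, and 0.90 at adjusted p = 0.00707 with library size alone) and Atp7a (0.34 ± 0.21, and 0.84 at adjusted p = 0.0123 with library size alone) did not pass. Atp7b changed by -1.23 ± 0.36 (adjusted p = 0.0237) and lost its call without uIRI+MSC 1 (0.0528), uIRI+MSC 2 (0.0639), uIRI+MSC 3 (0.0519) or sham 1 (-0.63, adjusted p = 0.292), with library size alone (0.112) and with a replicate block (0.0764).

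Liver-listed genes went both ways, with 3 lower, among them Alb (-2.96 ± 0.59), and 2 higher (median -1.43, camera adjusted p = 0.39). Of the higher ones Fgb (2.44 ± 0.74) lost its call without uIRI+MSC 2 (0.0677), sham 1 (0.151) or sham 2 (0.0976), and with limma-voom (0.0520). Erythrocyte genes (median -1.19, adjusted p = 0.25) were called without sham 1 (median -1.90, adjusted p = 0.011) and had a median of 0.46 without sham 2 and -2.16 without uIRI+MSC 2. The 4 adipocyte genes (median -0.41, mean 0.10, and a median of 0.11 with library size alone), the 4 skeletal muscle genes (median 0.83, or 1.43 without sham 1 and 2.00 without sham 2, mean -0.67, camera leaning down), the 4 Y-linked genes (median -0.13, 0.38 with library size alone) and the adrenal genes Cyp21a1 and Star were not called. In all camera called 26 of 38 lists, 11 higher and 15 lower, fry 30, and its mixed form 35.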

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

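Calls against sham held under most alternatives. With library size alone, 6697 of the 9044 genes called in uIRI against sham were still called, 25 of them in the opposite direction. In uIRI+MSC against sham 5023 of the 7029 were. The count of genes changed in uIRI against sham ran from 6386 to 9863 when 1 library was left out (9044 with all). In uIRI+MSC against sham it ran from 3938 to 6914 (7029 with all), lowest without sham 1, where the lone sham library is assumed to vary like the other groups, and it was 4476 when a change of at least 2-fold was also asked. In uIRI+MSC against uIRI it was 0 with all libraries and 0 to 8 when 1 was left out, 1341 with DESeq2 in place of edgeR, and 16 without uIRI 1 and uIRI+MSC 3 together. The cause was not tested.

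With library size alone as the scaling, Eif2s3y, Kdr and Uty turned from -0.52, -0.54 and -0.48 to 0.15, 0.12 and 0.19 in uIRI against sham, since that scaling moves the median gene from 0.06 to 0.73. The copper list in uIRI against sham, with its median of -0.16, passed as higher with fry (adjusted p = 0.013), which does not set the list against other genes. With an estimated correlation camera called 0 lists in uIRI against sham, 0 in uIRI+MSC against uIRI and 0 in uIRI+MSC against sham, and fry called 3 in uIRI+MSC against uIRI in place of 18. Leaving out 1 library gave 26 to 30, 14 to 22 and 25 to 28 lists in the 3 comparisons.

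Of 176 genes named in uIRI against sham, 152 kept the same call under every alternative, 12 became weaker under at least 1 and 12 stronger. The same figures were 150, 19 and 8 of 177 in uIRI+MSC against sham. In uIRI+MSC against uIRI they were 91, 0 and 70 of 161, where the stronger calls came with DESeq2 or without some libraries. As 0 genes were called there in the main fit, a weaker call was not possible. The 91 were thus genes called under no setting, which is no measure of stability.

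A replicate block, in which libraries of the same number form a block, gave 7959, 0 and 5753 genes and 28, 17 and 28 lists. It ended the call of OXPHOS complex II in uIRI+MSC against uIRI (adjusted p = 0.052) and added those of intercalated cells in uIRI against sham (0.047) and of principal cells (0.017) and mitochondrial biogenesis (0.041) in uIRI+MSC against sham. The labels do not say that libraries of the same number were paired. Residuals of same-number libraries of different groups correlated between -0.21 and 0.11, those of other numbers between -0.20 and 0.21, and 0 of 8 libraries matched best with their own number.

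In simulated data with 200 genes changed, a 2-fold change was recovered in 17.9, 32.8 and 32.8% of genes in the 3 comparisons. A 4-fold change was recovered in 69.7, 78.8 and 75.8%, and a 1.5-fold change in 1.5, 0.0 and 3.0%. Most changes of 2-fold and nearly all of 1.5-fold were thus missed in data with few changed genes. The adjusted p is less strict where many genes change, so these shares do not carry over to the comparisons with sham. There 9044 genes passed in uIRI, 6037 of them changed at least 2-fold, and 7029 in uIRI+MSC, 4476 of them at least 2-fold. Smaller changes were thus called there as well. Alternatives made for normalized values, namely a pseudocount, a filter on low values, rescaling by median ratios of the deposited values and quantile normalization, were not run, since counts were used. The scaling by library size alone, edgeR with legacy=FALSE, the other scalings of the lists and leaving out uIRI 1 and uIRI+MSC 3 together were added after the data were seen.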

Other observations

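These families and genes were looked at only after the results were seen. Of 20 genes of cholesterol synthesis, 16 were lower in uIRI and 16 in uIRI+MSC than in sham (median log2 changes -0.93 and -1.05, or -0.26 and -0.54 with library size alone). All 9 genes of MHC class II rose in both (3.45 and 3.05), and 10 and 9 of 13 Cxcl chemokine genes (3.27 and 3.95). Chemokine genes named Ccl were not in this set. Of 20 Cyp2 genes 15 were lower and 3 higher in uIRI than in sham (median -2.21). In uIRI+MSC against uIRI their median was 0.87, with 16 of 20 above 0, but 0 passed edgeR. Of 17 histone genes 10 were lower in each injured group (-1.66 and -1.29), whose transcripts mostly lack the poly(A) tail used to isolate mRNA.

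Of the genes called in uIRI against sham, 980 with a mean log2 CPM over 3 and an unadjusted p under 0.01 between uIRI+MSC and uIRI lay nearer sham in uIRI+MSC, and 10 further from it. Both comparisons use the uIRI libraries. Data simulated without an effect of MSC gave 51.5 nearer (38 to 62 in 20 draws) and 31.2 further (21 to 40). The 10 are fewer than in those draws, but each gene was drawn independently. A shift shared by many genes could move both counts without an effect of MSC, so the draws do not settle this. Among the 10 were Vcam1 (14.7, 438 and 786 CPM in sham, uIRI and uIRI+MSC), the complement gene C3 (33.3, 993 and 2400), Cfi (13.8, 32.3 and 75.1), the osteopontin gene Spp1 (996, 5420 and 10700), the carboxypeptidase gene Cpe (55.4, 150 and 237), Sorcs1 (0.189, 12.1 and 21.1), Gpc3, Pprc1, and in the other direction the creatine kinase gene Ckb (239, 111 and 71.2). None of the 10 passed edgeR over all genes. DESeq2 called 1248 of the genes changed in uIRI against sham, 15 of them in the direction of that change and 1233 in the opposite direction.

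The count of genes separating uIRI+MSC from uIRI depended on the tool, and the splits of the 6 injured libraries used here were chosen for edgeR only after the result was seen. With edgeR the real grouping gave 0 genes and the highest other grouping 3, and as any count is at least 0, the 10 of 10 splits that reach it carry no weight. With DESeq2 the real grouping gave 1341 and the highest other 71, so 1 of 10 did, and with gene lists called by camera the real grouping gave 18 and the highest other 18, so 3 of 10 did. The splits are too few for a share under 0.05. An effect of the transplanted cells stays open as a hypothesis that these counts do not settle, and more animals per group would test it.

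That the changes of uIRI+MSC against uIRI ran opposite to those of uIRI against sham in 87.0% of called genes could come from the uIRI libraries that both share, from uIRI 1 alone, or from fewer infiltrating cells, and the tests of the latter 2 were chosen only after the result was seen. With no uIRI library in common the lowest share was 84.3%, which speaks against sharing as the whole cause. Without uIRI 1 the share was 84.2%, which speaks against that library alone. If only fewer infiltrating cells diluted the kidney's own transcripts less, podocyte genes might lie higher as proximal tubule genes do, yet 1 of 10 podocyte genes lay above 0 against 32 of 32 proximal tubule genes. Less severe injury in these kidneys from the start and repair after transplantation stay open and were not tested, with injury markers on both sides, as Lcn2 lay nearer sham (156 against 231 CPM in uIRI), Havcr1 further (885 against 311 CPM), and neither passed edgeR.

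Nuclear OXPHOS genes lay near 0 in uIRI+MSC against uIRI (median 0.13) while genes of mitochondrial DNA lay higher (1.00), and both tests of it were chosen only after this pattern was seen, with predictions written before they were run. Loss of short transcripts in uIRI+MSC 3 may hide a rise, since these 95 genes have a median transcript length of 716 bases and their median without it was 0.29, with 90 of 95 above 0, just short of the value set beforehand. Part of this rests on uIRI 1, as the medians of complexes I, III, IV and V were 0.18, 0.23, 0.20 and 0.17 without both libraries, against 0.30, 0.39, 0.28 and 0.28 without uIRI+MSC 3 alone. Ribosomal protein genes, of similar length (713 bases), went from -0.24 to -0.04, and those of the TCA cycle, of 1714 bases, from 0.51 to 0.53. The pattern also rests on uIRI+MSC 1, without which complexes I, III, IV and V had medians of -0.13, -0.21, -0.13 and 0. Relative to their group mean, nuclear OXPHOS genes had a median of 0.37 in uIRI+MSC 1 and -0.46 in uIRI+MSC 3. Ribosomal protein genes had medians of 0.34 and -0.54 there. The reading stays open, because leaving out uIRI+MSC 3 removes any other trait of it as well. A rise of the mitochondrial DNA genes from uIRI+MSC 3 alone is unlikely, as their median without it was 0.65, and 0.46 without uIRI 1 as well.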
